A study of Drosophila melanogaster with 6 samples.

How the data were processed

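RNA from whole larvae was profiled on 6 single-channel arrays, 3 from pex1 homozygous mutants and 3 from wild-type larvae. Per the labels' protocols, eggs were collected over 30 minutes and kept at 25 °C in air of 70% humidity for 48 hours, after which mutants were picked by hand as moving larvae without the fluorescent marker of the TM3 balancer chromosome. Wild-type larvae came from parents that carried w1118 over the same balancer; the labels do not say whether these larvae were also picked for lacking the marker. One label calls the larvae freshly hatched. RNA was taken from samples of 200 mg and 100 ng of it was labelled with biotin by in vitro transcription from the 3' end.

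The deposited values are signal intensities per probe set on a linear scale, one column per array. Per the submitters' processing notes they were made with MAS5, whose version is not given in the sources used here. How the arrays were scaled, which filters were applied and which genome build lies behind the probe sets are likewise not given in the sources used here. No detection calls were in the table. The table held 648 probe sets with signals from 0.382 to 28117. Tested on the table itself, the ratio of the 2 genotypes' mean signals was at least 3 in every row, in either direction, and 0 rows fell under that limit. A two-group test on the linear signals gave p values up to 0.358, so no filter on such a p is visible. There were 0 columns of samples outside the series.

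Probe sets were named through the platform annotation table supplied with the series. Of the 646 probe sets tested, 528 had 1 symbol (515 distinct genes), 30 had several and 88 had none. Of the 528, 527 were found in the RefSeq gene table by gene identifier, and no symbol needed an update. No gene was named from a probe set with several symbols. Probe sets with the suffixes _s or _x can match more than 1 transcript. Of 13 genes with more than 1 probe set, 0 had probe sets that disagreed in direction, and the probe set with the smallest p was used for naming.

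Signals were taken to log2 with no offset, and the 2 control probe sets were left out. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the genotype as the only term and Benjamini-Hochberg adjustment over the 646 probe sets, at an adjusted p of 0.05. Log2 changes are mutant minus wild type, and folds are ratios of geometric means. Because the rows were chosen for a difference between these same arrays, the adjusted p values are too small, within the list as well as over the array. The threshold therefore does not fix the share of false calls.

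The plan fixed before the data were examined made centring of the arrays on their medians the main fit if the medians differed by over 0.5 on the log2 scale, as they did. That rule assumed that most rows were unchanged. In a table where every row was chosen for a difference, centring subtracts the difference itself, so the values were used as deposited and centring was kept as an alternative, which is a departure from the plan. The deposited values had a median change of -2.02 over all rows, against -0.39 after centring.

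The 27 gene lists were fixed before the data were examined. Members were matched by current symbol, or by a synonym that belongs to 1 gene alone, and some lists used symbol prefixes. Lists with at least 5 probe sets were tested with limma's camera (preset correlation 0.01, Benjamini-Hochberg over the 7 lists tested), with a correlation estimated per list and limma's fry as alternatives. Camera sets a list against the other rows of the same chosen table. Fry tests whether a list moves one way and compares it with nothing else. The text names CG1441 and the peroxin search, the 12 genes with the largest rise and the 12 with the largest fall among those with an adjusted p under 0.05 and no overlap between genotypes, and up to 4 genes with the smallest p from each list with at least 2 members. Single members of other lists and members that moved against their list or did not pass are named as exceptions, as are further members of the immune and cuticle lists and of the elongase list, and these were chosen after their values were seen.

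Alternatives fixed in advance were centring, quantile normalization, an offset of 50 before the log, leaving out the dimmest 25% of probe sets, the replicate number as a block, limma with trend and robust settings, leaving out each array, averaging probe sets per gene, a 2-fold limit, an adjusted p of 0.01 and a test without moderation. A test with unequal variances, a weight per genotype and an exact test of the direction split per list were added after seeing the data. The fit was tested on simulated data for this comparison (646 probe sets, 200 of them changed, 20 runs). It recovered 35.5% of 2-fold, 64.3% of 4-fold and 89.2% of 16-fold changes, and 4.81% of its calls were false. The simulated rows had the same spread in both genotypes and were not chosen for a difference. These shares therefore do not describe the calls made on the real table.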

Results

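Transcript levels were measured on Affymetrix-type 3' expression arrays in whole larvae of Drosophila melanogaster that were homozygous for a mutant allele of pex1 (gene l(3)70Da), which encodes a peroxin, a protein of peroxisome assembly. Wild-type larvae were the comparison, and the labels do not say whether carriers of the TM3 balancer chromosome were left out of them. Each genotype was represented by 3 arrays, which the labels call biological replicates. The labels do not say whether the replicates came from separate crosses, so p-values measure the spread between these samples, part of which may be technical. The value table held 648 probe sets. In every one of them the mean signals of the 2 genotypes differed by a factor of at least 3 (smallest ratio 3.00005), so the table is a list chosen for change on these same arrays. Counts given here are therefore counts within that list and say nothing about how much of the array changed. A measured gene here means a gene named in that list. Whether other members of the gene lists fell short of that factor or had no probe set of their own cannot be told from it. The chosen folds are likely to be somewhat too large, and the adjusted p values are too small for the same reason. After 2 control probe sets were left out, 646 probe sets were tested, of which 528 carry 1 gene symbol, 30 carry several and 88 carry none in the annotation used. The median signal over the tested probe sets was 440.4, 445 and 434 on the wild-type arrays and 91.2, 214 and 146 on mutant replicates 1, 2 and 3. The number of arrays limits the precision. No genomic coordinates are given, since the build behind the probe annotation is not given in the sources used here.

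The comparison asks which transcripts differ in larvae homozygous for this pex1 allele. Peptides of the immune response were among the transcripts that rose most, with BomBc2 up 79.9-fold from a wild-type signal of 3.15 that carries no detection call (5.64-fold with an offset of 50 added to each signal). Among probe sets with 1 gene symbol, the new glue gene ng2 had the largest fall, of 72.2-fold, while 2 probe sets that carry no symbol fell 146-fold and 120.3-fold. On mutant replicates 1, 2 and 3 the former was at 0.512%, 2.37% and 0.263% of the wild-type mean and the latter at 0.211%, 6.96% and 0.390%. The sizes of these 2 folds are therefore uncertain. Many genes for cuticle proteins fell, with Lcp9 down 64.2-fold and TwdlK down 53.9-fold. In limma's moderated test on log2 signal, with Benjamini-Hochberg adjustment over the 646 probe sets, 591 passed an adjusted p of 0.05, 196 of them higher and 395 lower in the mutant. Of the 234 probe sets higher in the mutant, 38 did not pass, and of the 412 lower ones, 17 did not. The median change was 4.26-fold among the higher probe sets and 5.95-fold among the lower ones. The 3 mutant values lay wholly above or below the 3 wild-type values in 599 probe sets, or 92.7%, where chance alone gives 10% in probe sets not chosen for change. Because the array medians differ, the split depends on the scaling: with each array centred on its median, 229 probe sets passed as higher and 149 as lower, and the median change over all 646 moved from -2.02 to -0.39 on the log2 scale; with quantile normalization 160 passed as higher and 190 as lower.

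None of the listed probe sets is annotated to a peroxin. Pex1 itself and the other 14 peroxin genes looked for were therefore not analysed here, and the array data give no check of the genotype labels from the mutated gene. The single member of the list of peroxisomal enzymes and transporters in the table was CG1441, which belongs to the fatty acyl-CoA reductase family. It fell by 2.45 ± 0.20 (SE) on the log2 scale, from a signal of 3372 ± 256 (SD, n = 3) in the wild type to 615 ± 30.0 (SD, n = 3) in the mutant, with an adjusted p of 0.000316 in limma. It did not pass with arrays centred on their medians or with quantile normalization, at log2 changes of -0.82 and -0.71. No probe set of the lists for mitochondrial fatty acid oxidation, fatty acid synthesis and lipid storage, glycolysis and trehalose metabolism, the mitochondrial respiratory chain, the proteasome, ribosomal proteins, nucleolar ribosome biogenesis, the cell cycle, heat shock proteins, glia, muscle or genotype and sex markers was in the table, so these were not analysed here.

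The genes of the antimicrobial and immune response that were in the table all rose in pex1 mutant larvae. Of the 72 genes of this list, 10 were in the table, which holds only rows chosen for change. All 10 passed the test as higher, both over all probe sets and adjusted over the list alone, with a median rise of 12.2-fold. All 10 also passed with arrays centred on their medians, with quantile normalization and with an offset of 50 added to each signal, and the median rise was then 37.8-fold, 23.6-fold and 5.96-fold. Of these, 7 encode Bomanins, short secreted peptides induced by Toll signalling. BomBc2 rose 79.9-fold, from a signal of 3.15 ± 0.542 to 250.1 ± 22.99 (SD, n = 3 each). BomS2 rose 66.6-fold, from 15.98 ± 3.72 to 1083 ± 338, and BomS6 rose 59.7-fold, from 17.9 ± 7.86 to 1022 ± 268. BomS5 rose 32.2-fold and BomS4 13.9-fold, while BomT2 and BomT3 rose 10.7-fold and 10.2-fold. The antimicrobial peptide genes Mtk (Metchnikowin), Drsl2 (Drosomycin-like 2) and Drs (Drosomycin, an antifungal peptide) rose 8.94-fold, 7.76-fold and 5.56-fold. The adjusted p was 0.00166 in limma for Drs and lower for each of the other 9. In limma's camera test against the other listed probe sets the shift of the list had an adjusted p of 1.99e-06, and an adjusted p of 0.0395 with an estimated correlation. The low wild-type signals of the Bomanin genes carry no detection call here, so the sizes of their folds are uncertain: with the offset BomBc2, BomS2, BomS6 and BomS5 rose 5.64-fold, 16.6-fold, 15.5-fold and 11.8-fold, and BomS4, BomT2 and BomT3 rose 6.30-fold, 3.21-fold and 1.73-fold.

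Cuticle protein genes and genes of chitin metabolism were mostly lower and made up the largest of the fixed lists in the table. Of the 170 genes of this list, 72 were in the table. Of these, 65 passed as lower, 2 passed as higher and 5 did not pass, with the same counts when adjusted over the list alone. With arrays centred on their medians 32 passed as lower, and with quantile normalization 36, with 2 higher in each case. The list median was a fall of 8.76-fold, or -3.13 on the log2 scale, and was -1.50 with arrays centred on their medians and -1.79 with quantile normalization. The Tweedle family of cuticle proteins had 20 of 21 measured genes passing as lower, with a median fall of 10.5-fold and a median log2 change of -3.40, or -1.76 with centring; 9 passed with centring and 8 with quantile normalization. The Cpr family, whose proteins bind chitin through the Rebers and Riddiford motif, had 29 of 33 passing as lower, with a median fall of 7.80-fold and a median log2 change of -2.96, or -1.33 with centring; 15 passed with centring and 19 with quantile normalization. Cpr47Ee, which did not pass, turned to 0.11 with centring and passed with quantile normalization, at -2.10. TwdlK fell 53.9-fold, from a signal of 11881 ± 507 to 247 ± 151 (SD, n = 3 each). Lcp9, a larval cuticle protein gene, fell 64.2-fold, from 1009 ± 66.8 to 20.05 ± 12.9. Cpr60D fell 49.7-fold, and Cpr62Bc, which had the smallest p of the list, fell 10.6-fold. Cpr65Ec fell 9.54-fold and Edg78E fell 7.98-fold. The chitin deacetylase genes verm and serp fell 4.26-fold and 3.79-fold, but neither passed with arrays centred on their medians, at log2 changes of -0.46 and -0.29, nor did verm with quantile normalization, at -0.62. The chitinase genes Cht7 and Cht6 fell 5.07-fold and 3.04-fold, although Cht7 did not pass with centring, at -0.71, and Cht6 turned to log2 changes of 0.03 with centring and 0.18 with quantile normalization. Over the 7 measured genes for chitin enzymes and related proteins, the median log2 change was -1.89, -0.26 with centring and -0.13 with quantile normalization, so their fall depended on the scaling. Cht4, another chitinase gene, and obst-G, which encodes a chitin-binding protein, were the 2 members that rose, by 4.90-fold and 3.09-fold. The genes that did not pass were TwdlQ, Cpr64Ab, Cpr66D, Cpr47Ee and Cpr23B, with log2 changes of -3.60, -2.61, -2.67, -1.52 and -3.31. The camera test gave an adjusted p of 7.13e-06 for the list, and an adjusted p of 0.678 with an estimated correlation, so that call is lost. Without mutant replicate 1 the list median was -2.34 on the log2 scale, against -3.13 with all arrays.

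**Figure D1:**
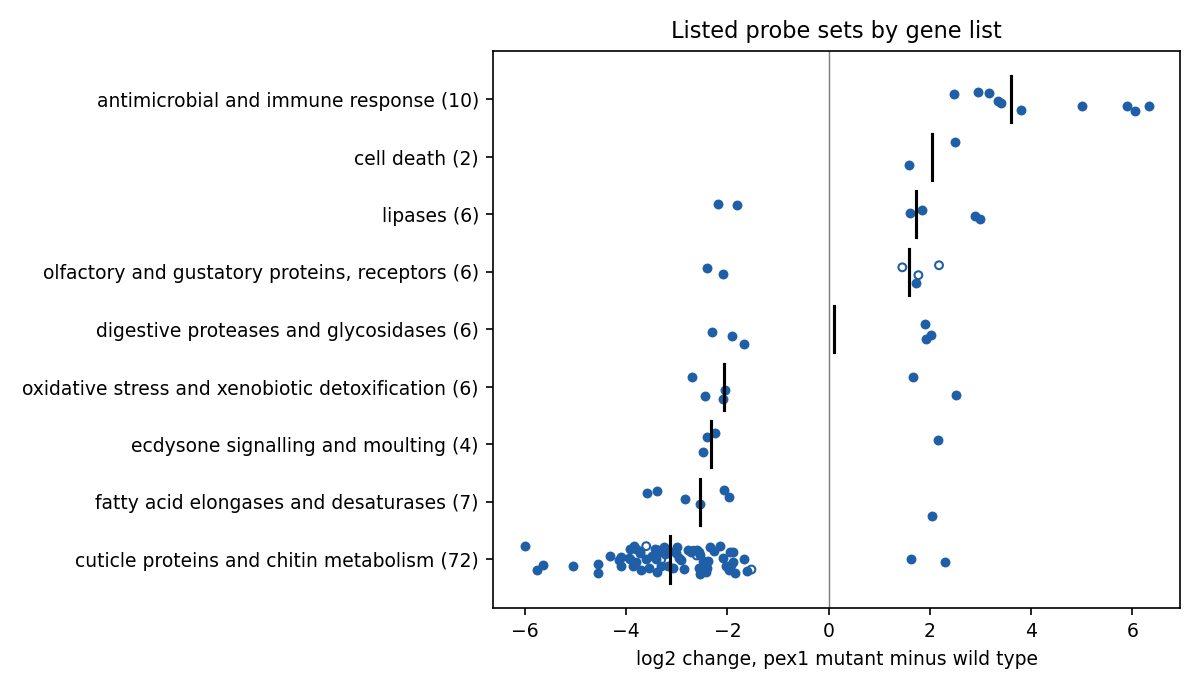
Log2 change in signal (pex1 mutant minus wild type, x axis) of each listed probe set, by gene list (y axis, number of probe sets in parentheses). Filled points passed an adjusted p of 0.05 in limma, open points did not, and black bars are list medians; all 10 immune probe sets lie to the right of 0, and 70 of the 72 cuticle probe sets lie to the left (68 with arrays centred on their medians).

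Outside these lists, the genes with the largest rises included several known only by CG numbers. CG14453 rose 51.2-fold, from a signal of 12.6 ± 1.42 to 684 ± 277 (SD, n = 3 each). CG13946, CG12506 and CG13461 had far higher signals and rose 29.3-fold, 13.05-fold and 12.7-fold. CG13946 reached 12982 ± 1763 in the mutant against 441 ± 44.1 in the wild type. Bace, a homologue of the beta-secretase genes, rose 21.3-fold, from 174 ± 18.2 to 3712 ± 468. The transcription factor gene rib rose 13.7-fold. With an offset of 50 added to each signal, the log2 changes of CG13946, Bace, CG14453 and rib were 4.72, 4.07, 3.47 and 2.95, against 4.88, 4.41, 5.68 and 3.78 without it, and that of CG14238 was 0.59 against 3.58. CG14238 rose 11.96-fold with an adjusted p of 0.0229 in limma, but its wild-type signal was 5.11 ± 6.36. Its call was lost without mutant replicate 1, 2 or 3 or without wild-type replicate 1, with adjusted p values of 0.0533, 0.0733, 0.0508 and 0.0599, and its fold was 26.0 without wild-type replicate 2 and 5.91 without wild-type replicate 3.

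The genes with the largest falls among probe sets with 1 symbol, besides TwdlK, Lcp9 and Cpr60D, were the new glue gene ng2, which encodes a secreted protein of the salivary gland, and 8 genes known by CG numbers. The signal of ng2 fell 72.2-fold, from 3628 ± 82.8 to 162 ± 224 (SD, n = 3 each). CG13060 fell 70.6-fold, CG13226 fell 58.4-fold and CG14324 fell 58.4-fold, while CG14326 fell 55.0-fold. CG13041, CG14564, CG42819 and CG17290 fell 43.2-fold, 40.7-fold, 40.1-fold and 38.7-fold. The mutant arrays differed widely at these genes, and mutant signals of a few units carry no detection call, so the sizes of the folds are uncertain: with an offset of 50 added to each signal the log2 changes of ng2, CG13060, Lcp9 and CG13226 were -4.69, -4.59, -3.93 and -3.42, and that of TwdlK was -5.44. The fall of ng2 was 22.6-fold without mutant replicate 1 and 208-fold without mutant replicate 2. Without mutant replicate 1, CG13060 fell 35.9-fold, CG13226 fell 30.7-fold, CG17290 fell 16.4-fold and CG14326 fell 95.7-fold. Without mutant replicate 2, CG13226 fell 146-fold, CG17290 fell 70.8-fold and CG14326 fell 31.4-fold. Without mutant replicate 3, Lcp9 fell 36.6-fold, CG14324 fell 34.4-fold and CG14564 fell 26.8-fold. All of these calls held in each case.

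**Figure D2:**
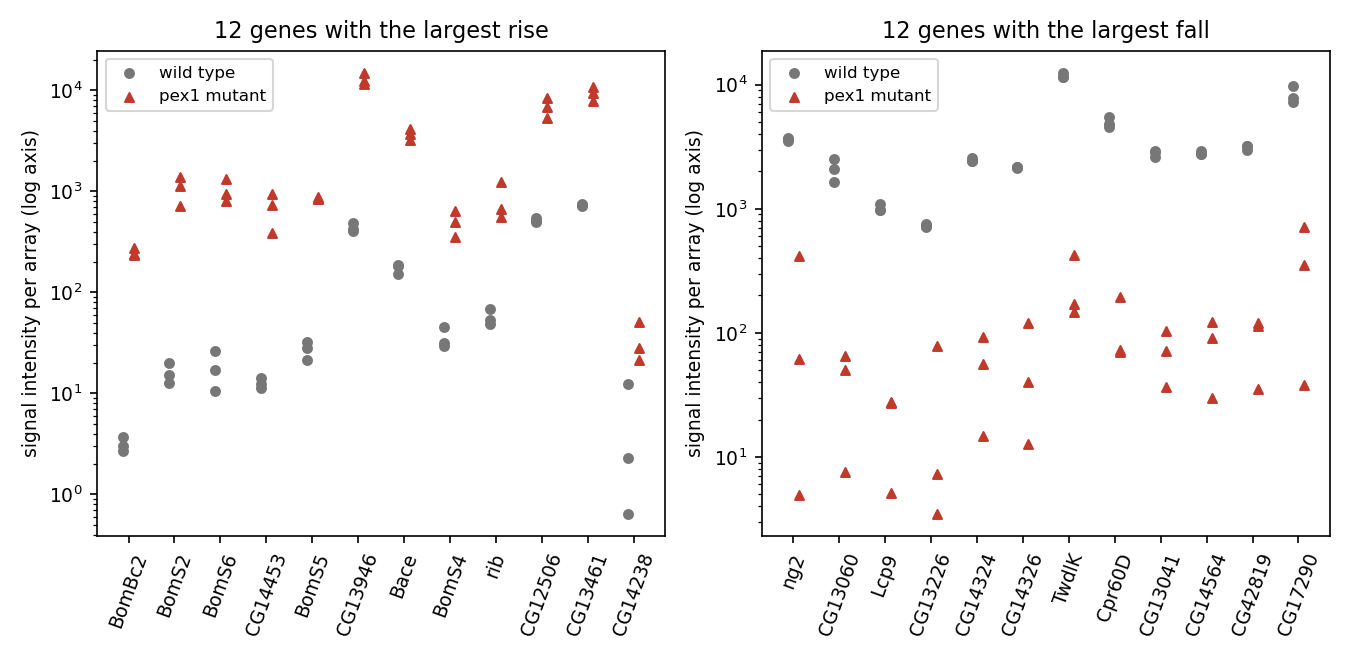
Signal intensity per array (log axis) of the 12 named genes with the largest rise and the 12 with the largest fall that passed the test without overlap between genotypes; circles are wild-type arrays and triangles are pex1 mutant arrays, 3 each. The mutant signals of ng2 run from 4.91 to 418, while its wild-type signals run from 3537 to 3698.

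Fatty acid elongase genes, which lengthen fatty acid chains, were mostly lower. The list of elongases and desaturases held 7 probe sets of 6 genes, of which 6 probe sets passed as lower and 1 as higher, over all probe sets and adjusted over the list alone. CG33110 fell 10.5-fold, from a signal of 3427 ± 79.6 to 337 ± 107 (SD, n = 3 each). The elongase genes sit and CG5326 fell 7.19-fold and 5.83-fold, and Elo68alpha passed as lower at signals of 31.9 ± 9.66 in the wild type and 4.17 ± 4.93 in the mutant, which carry no detection call, so the size of its fold is uncertain. Of the 2 desaturase genes, CG8630 fell 3.90-fold and CG9743 rose 4.11-fold. With arrays centred on their medians, sit, CG5326 and CG8630 kept their sign but no longer passed, at log2 changes of -1.21, -0.91 and -0.33, nor did they with quantile normalization, at -1.09, -0.89 and -0.67. With either scaling 2 of the 7 probe sets passed as lower. The list as a whole did not pass camera, with an adjusted p of 0.305.

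Lipase genes and genes of protein and carbohydrate digestion went both ways. Of 6 lipase genes, 4 passed as higher and 2 as lower, over all probe sets and adjusted over the list alone. Lip3 rose 7.46-fold, from a signal of 289 ± 7.18 to 2165 ± 242 (SD, n = 3 each), and CG5162 rose 3.60-fold. CG5665 and CG6472 fell 4.56-fold and 3.52-fold, and with arrays centred on their medians neither passed, at log2 changes of -0.56 and -0.18, nor with quantile normalization, at -1.21 and -0.83. Of 6 digestive protease and glycosidase genes, 3 rose and 3 fell, again with the same counts when adjusted over the list alone. The amylase-related gene Amyrel rose 4.06-fold, from 1854 ± 29.05 to 7534 ± 301, the maltase gene Mal-A4 rose 3.75-fold and the trypsin gene alphaTry rose 3.78-fold, while Try29F fell 4.95-fold. Centring ended the calls of all 3 lower members, with Try29F at a log2 change of -0.67, and quantile normalization left 1 of them. Camera gave adjusted p values of 0.242 for the lipases and 0.478 for the digestive list, whose median was 0.12 and mean -0.0087 on the log2 scale.

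Genes timed by the steroid hormone ecdysone were among the listed transcripts. Of the 43 genes of the ecdysone and moulting list, 4 were in the table. Of these, 3 fell and 1 rose, over all probe sets and adjusted over the list alone. The nuclear receptor gene ftz-f1 fell 4.75-fold, from a signal of 1250.5 ± 20.7 to 264 ± 22.8 (SD, n = 3 each). The ecdysone-inducible genes ImpE2 and ImpE1 fell 5.57-fold and 5.29-fold. ImpE1 passed with all arrays (adjusted p = 0.0219 in limma). It lost its call without mutant replicate 3 or wild-type replicate 1, 2 or 3, with adjusted p values of 0.0530, 0.0503, 0.0564 and 0.0579, and its fall was 3.11-fold without mutant replicate 1 and 8.37-fold without mutant replicate 2. Npc2e, which belongs to a family of sterol-binding proteins, was the member that rose, by 4.48-fold. With arrays centred on their medians, ftz-f1 and ImpE1 did not pass, at log2 changes of -0.61 and -0.77. With quantile normalization ftz-f1, ImpE1 and ImpE2 did not pass, at -0.53, -1.46 and -0.66. Of the 18 genes of the cell death list, 2 were in the table. Both encode caspases, and both rose. Damm rose 5.65-fold, from 89.7 ± 15.3 to 549 ± 246, and Strica rose 3.02-fold, from 270.4 ± 24.2 to 817 ± 84.4.

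Detoxification genes were split, with 2 passing as higher and 4 as lower, over all probe sets and adjusted over the list alone. The glucuronosyltransferase family genes Ugt37A1 and Ugt302E1 rose 5.70-fold and 3.17-fold, while Ugt35B1 and the cytochrome P450 gene Cyp4c3 fell 4.25-fold and 6.46-fold. With arrays centred on their medians none of the 4 lower members passed, and 1 did with quantile normalization. With centring Ugt35B1 and Cyp4c3 did not pass, at log2 changes of -0.45 and -1.06, and Cyp4c3 did not with quantile normalization, at -0.96. The median of the list was -2.07 and its mean -0.85 on the log2 scale, whereas camera placed it upward against the other listed probe sets with an adjusted p of 0.932. Of 6 probe sets of odorant-binding proteins and chemoreceptors, 1 passed as higher, 2 as lower and 3 did not pass, over all probe sets and adjusted over the list alone, and camera gave an adjusted p of 0.478. Obp56d, the brightest, fell 5.25-fold, from 14687 ± 980.4 to 2993 ± 1375 (SD, n = 3 each), Obp99b fell 4.25-fold and Obp56e rose 3.29-fold. Obp99b did not pass with centred arrays, at a log2 change of -0.46. Obp73a did not pass at a log2 change of 1.77 (adjusted p = 0.0702 in limma), but it passed without wild-type replicate 2, at 2.49, with centred arrays, at 3.41, and in the fit with the replicate number as a block (adjusted p = 0.0139). Grik, which was caught by the prefix used for gustatory receptors, encodes a glutamate receptor subunit and did not pass, at a log2 change of 2.18, nor did the gustatory receptor gene Gr22d, at 1.46, which passed with centring, at 3.09.

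Markers of other tissues were nearly absent from the list. The neuronal list had 1 member, the synaptic vesicle gene nSyb, at a log2 change of 2.14 that did not pass (adjusted p = 0.0552 in limma) but did with centring, at 3.77. The haemocyte list had 1, PPO1, a phenoloxidase gene of crystal cells, which fell 3.27-fold but did not pass with centring, at a log2 change of -0.07, or with quantile normalization, where its sign turned, at 0.07. The starvation and FOXO list had 1, the insulin-like peptide gene Ilp5, which fell 4.73-fold, from a signal of 330.0 ± 16.05 to 78.7 ± 48.7 (SD, n = 3 each), but did not pass with centring or quantile normalization, at log2 changes of -0.61 and -0.80. The fat body list had 1, Obp99b, which is also counted among the odorant-binding proteins.

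The mutant arrays differed more among themselves than the wild-type arrays did. Over the tested probe sets the correlation of log2 signal between arrays was 0.971 to 0.977 within the wild type and 0.826 to 0.931 within the mutant. The median SD of log2 signal over 3 arrays was 0.637 in the mutant and 0.116 in the wild type, and the mutant SD was the larger in 529 of the 646 probe sets. The first principal component held 83.4% of the variance and separated the genotypes, which follows from the choice of rows for that difference. On it mutant replicate 1 lay farthest from the wild type and mutant replicate 2 nearest. The control probe sets AFFX-Dm-M62653-1_s_at and AFFX-Dm-AF292560-1_s_at, which carry no gene name in the tables used, had signals of 3862 ± 427 and 3409 ± 203 (SD, n = 3) in the wild type. On mutant replicates 1, 2 and 3 the former had 10.8, 945 and 145 and the latter 6.65, 755 and 106. Among the 412 probe sets lower in the mutant, which include 70 of the 72 cuticle probe sets, the median signal was 10.5%, 25.5% and 17.2% of the wild-type mean on mutant replicates 1, 2 and 3.

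**Figure D3:**
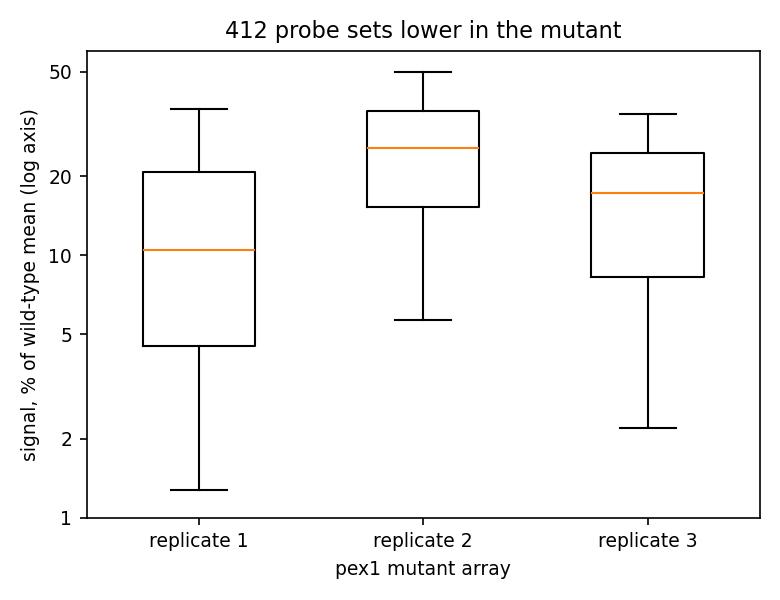
Signal as a percentage of the wild-type mean (log axis) for the 412 probe sets lower in the mutant, on each of the 3 mutant arrays; boxes span the quartiles, the line is the median and whiskers reach the 5th and 95th percentiles. The medians are 10.5%, 25.5% and 17.2% on replicates 1, 2 and 3.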

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

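Some settings were added after seeing the data, namely the test with unequal variances, the weight per genotype and the direction split; the others were planned. The count of 591 probe sets (196 higher, 395 lower) changed by over 1.5 times with the scaling between arrays and with a test of unequal variances. It fell to 378 (149 of them lower) with arrays centred on their medians and to 350 (190 of them lower) with quantile normalization. Both settings remove a difference for which the rows had been chosen, and the higher share of the called probe sets went from 33.2% to 60.6% and 45.7%. Of the 591 calls, 345 and 347 kept call and direction under these settings, and the sign turned in 3 and 15, none of them with a call. Without the dimmest 25% of probe sets, which leaves fewer to test, 126 higher ones passed, all that remained. The test with unequal variances passed 342 (210 of them lower), and with a weight per genotype 121 higher ones passed; the cause was not tested. Leaving out 1 array gave 522 to 574 calls, 166 to 184 higher and 347 to 398 lower. The other settings gave 438 to 591 calls. No sign that the replicate numbers pair the samples was seen: the deviations of same-numbered arrays correlated at -0.04, -0.05 and -0.04. With 3 arrays per genotype this cannot exclude a pairing. With the number as a block 590 probe sets passed, of which 575 were shared with the 591 calls. Of 7 lists tested, 2 passed camera, as they did under each normalization, filter, block and left-out array run; 1 passed with an estimated correlation and 5 with fry. Camera was not run with limma's trend setting. Of the 53 probe sets that the naming rule took, 10 lost their call under centring and 8 under quantile normalization, and 1 (Obp73a) gained one under centring; no sign turned. The mean correlation within the wild-type arrays was 0.974, and 0.970 after quantile normalization. With no detection calls, what dim signals limit could be seen only in part: among the 106 higher probe sets with a mutant mean under 100 in signal, 69 passed. Peroxin levels gave no value under any setting.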

Other observations

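Besides the lists, members of several small gene families were lower in the mutant; these were chosen after their values were seen and not tested for enrichment, in a table where 412 of 646 probe sets were lower. All 4 measured new glue genes, which encode secreted salivary gland proteins, passed as lower, with ng2 at a log2 change of -6.17, ng1 at -5.18, ng4 at -4.25 and ng3 at -3.81. On mutant replicates 1, 2 and 3 their signals, as a percentage of the wild-type mean, were 0.135%, 11.5% and 1.70% for ng2 and 0.394%, 16.7% and 3.19% for ng1. They were 6.20%, 8.10% and 2.92% for ng4 and 2.19%, 27.9% and 5.91% for ng3. Of 4 Osiris genes, Osi2 and Osi19 fell by 2.21 and 2.26 on the log2 scale, while Osi18 and Osi9 did not pass at -2.57 and -2.21. The cuticle barrier genes snu, osy and snsl fell by 2.08, 1.99 and 2.99, and the juvenile hormone binding protein family genes Jhbp12, Jhbp4 and Jhbp1 fell by 4.23, 2.75 and 1.87. On mutant replicates 1, 2 and 3 Jhbp12 was at 2.73%, 12.1% and 4.54% of the wild-type mean, Jhbp4 at 3.46%, 56.1% and 16.8% and Jhbp1 at 20.9%, 42.6% and 22.9%. Osi2 was at 7.43%, 41.9% and 32.1% and Osi19 at 5.86%, 53.7% and 28.8%. The scavenger receptor gene ninaD fell by 4.47, and the pigmentation gene y by 2.78. Burs, which encodes a subunit of the tanning hormone bursicon, rose by 1.60 in log2. These changes kept their sign under centring and quantile normalization, but several nearly vanished: the log2 changes were -0.24 and -0.05 for Jhbp1, -0.36 and -0.21 for osy, -0.44 and -0.31 for snu, and -0.58 and -0.36 for Osi2. Those of ng2 stayed at -4.54 and -5.02.

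For the patterns weighed below, the tests on the mutant arrays and on the cuticle list were chosen only after the results were seen; those on neighbouring genes and on other splits were fixed before.

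The mutant arrays varied more than the wild-type arrays, mostly at probe sets lower in the mutant. An array-wide scale difference and noise of dim signals are argued against: mutant replicate 2 exceeded replicate 1 by a median of 1.13 log2 at lower probe sets and by 0.12 at higher ones, a difference of 1.00 (95% bootstrap interval over probe sets 0.747 to 1.18), and in the 168 probe sets with a signal of at least 200 on every array the median SD was still 4.96 times as large in the mutant (interval 4.13 to 6.19). The 2 control probe sets AFFX-Dm-M62653-1_s_at and AFFX-Dm-AF292560-1_s_at showed the same order of arrays, at 0.281%, 24.5% and 3.76% and at 0.195%, 22.1% and 3.11% of the wild-type mean. If they report the balancer's fluorescent marker, wild-type-like larvae in mutant replicate 2 could be a source. Against the share of 22.1% that they give, 62 of 412 lower probe sets (15.0%, exact 95% interval 11.7 to 18.9) lay under 11.1% of the wild-type mean, 0.5 of that share, where almost none should. That share assumes that all wild-type larvae carried the marker alike, which the labels do not say. This interval and the bootstrap intervals above treat probe sets of the same arrays as independent. None of them measures the spread between larval collections. If they report that marker, their means of 3862 and 3409 in the wild type, against 10.8 and 6.65 on mutant replicate 1, mean that wild-type larvae carried the balancer. Every difference between mutant and wild type would then be confounded with the balancer. What the probe sets report was not tested. A smaller share, larvae that carry the balancer but differ from the wild type, and a difference in stage or health between the mutant collections stay open and were not tested.

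The fall of the cuticle list may reflect less epidermal RNA, a shift of the moulting cycle or altered cuticle gene expression. A loss of epidermal RNA that lowers every member by the same factor is argued against. The 70 lower genes had log2 changes with an SD of 0.968 against a median SE of 0.519. Their heterogeneity of 385 was 5.58 times the mean of 10000 simulations with the fitted errors, whose highest value was 117. The simulations assumed the same fall for all members and independent errors, so they cannot exclude a loss of epidermal RNA that reached members unequally. They also took the errors, which were fitted on 6 arrays, as known. Their values are therefore likely to be too low, and the ratio of 5.58 too high. Centring cannot decide whether array scaling was the whole cause, because every row was chosen for a difference. After centring the list median was -1.50 (-2.03, -1.04 and -1.09 on mutant replicates 1, 2 and 3), with 68 of the 72 members lower. But the 412 probe sets lower in the mutant had a median log2 change of -2.57 as deposited, and 406 probe sets were lower after centring. A list of mostly lower members was therefore bound to stay lower, and array scaling stays open. An uneven loss of epidermal RNA, a difference in developmental stage at collection and a direct effect of the genotype were not tested and stay open.

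Listed genes often lay next to each other in the genome: of 511 named protein-coding genes, 80 pairs were immediate neighbours in the RefSeq annotation (release 6 assembly), where 1000 random gene sets of that size gave 18.95 on average and 35 at most. The 2 genes changed in the same direction in 86.25% of the pairs, against 58.0% on average and 76.25% at most when directions were shuffled. The longest run held 6 genes, from Lcp65Af to Lcp65Ac, and another held ng2, ng3, ng1 and ng4, all lower. Probe sets marked for several transcripts are not a sufficient source, as 72 pairs were left without them (29 at most at random). Nor are the members of the cuticle list, as 57 pairs were left without them (25 at most). Any cuticle genes outside that list, such as ones known only by CG numbers, stayed in, so cuticle genes as a whole were not tested as a source. Tandem copies that cross-hybridise without such a mark, and shared regulation of neighbouring genes, were not tested and may both contribute; the array's own gene set, rather than all protein-coding genes, would be the better background.

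The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 591 probe sets, as did 1 of the 10 splits counting itself, and the highest of the others gave 0 in limma, on probe sets chosen for the real split; at an unadjusted p under 0.05 the real split gave 598 and the others 0 to 17. For the gene lists, 7 of the 10 splits gave as many lists in camera as the real one, 2 against 3 for the highest of the others. The immune list passed in each of the 10 splits. The cuticle list passed in those that put mutant replicate 1 with another mutant array, and had adjusted p values of 0.201, 0.118 and 0.283 in the 3 that put it with wild-type arrays alone. Each of the other splits sets 2 mutant arrays against 1, so part of the genotype difference remains in it and list calls there are no measure of chance.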
